A study of Rattus norvegicus with 6 samples.

How the data were processed

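Ventricular heart cells of newborn Wistar rats were grown to confluence and given 30 µM quercetin, a plant flavonoid, for 6, 12 or 24 h, per the labels. RNA of treated and untreated cells was amplified, labelled with Cy3 or Cy5 and hybridised together on rat oligonucleotide arrays of 21575 spots, of which 20500 carry non-control probes, each at 1 spot. The 6 arrays form 3 pairs, 1 per time point. In each pair array A holds the quercetin RNA in Cy5 and array B holds it in Cy3. Per the labels the second array repeats the first with the dyes exchanged, so a pair was counted as 1 replicate, and nothing in the labels says that the arrays of a pair come from separate cultures. The labels also do not say whether the 3 time points were set against 1 untreated RNA or against an untreated RNA of their own.

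Each array's file holds background-corrected and dye-normalised values that the authors made with Agilent Feature Extraction (version A.7.5.1), per the file headers, with spatial detrending as background and a linear and lowess dye normalisation on rank-consistent probes. The log ratio is a log10 of Cy5 over Cy3, per the file headers. The p-value beside each deposited log ratio and the error of the log ratio come from the same software's error model. The mean signals and local backgrounds are deposited intensity values of each channel. Where a log ratio was exactly 0, it was recomputed from the processed signals. Log ratios were converted to log2 and turned so that a positive value means more RNA with quercetin. Per the labels the authors then combined the arrays of a pair in other software and called sequences by fold and p. That combined table was not used here, and the call was rebuilt from the scanner files.

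Spots marked by the software as non-uniform or population outliers were left out. A probe was tested at a time point when the quercetin channel, or the untreated channel, was well above background on both arrays. Of the 20500 probes, 19586 were tested at 6 h, 18395 at 12 h, 19251 at 24 h and 17903 at all 3 times. Medians of the mean signal lay between 251.1 and 448, and 93.85% to 98.55% of probes in a channel were well above background. The small number of arrays limits the precision. Each array is a slide of its own, so no slide could be used as a block.

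Probes were named through the RefSeq accession in the array files, matched without versions to a table of the GRCr8 annotation, which named 3757 probes. A symbol in a rat description, either official or a synonym of 1 gene, named 159 more. The other 16584 probes have no symbol here and enter tests and counts without a name. No coordinates were used, since the files name no genome build. The value of a gene is that of its brightest probe. Of 101 genes with over 1 tested probe, 20 had probes of opposite sign in the average over times.

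At each time point the labels' rule was rebuilt as the mean of both log ratios weighted by their error, with a call at a fold of at least 2 and a p of at most 0.001. That p measures the error of these hybridisations and compares 1 pair of RNAs, not the conditions. Across time points, limma (version 3.58.1, R 4.3.3) tested the mean of the 3 dye-swap means against 0 (2 residual degrees of freedom) and their slope on log2 time (1 residual degree of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. If the untreated RNA was shared, these tests leave out the spread of the untreated cells. Of 28 gene lists, 26 had at least 5 measured genes and were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. For single time points the median of a list is given with its percentile among 10000 random lists of the same size matched on intensity in 20 bins. Where a channel was not well above background or was saturated on both arrays of a pair, a bound is given, from channel levels after normexp (offset 50), loess and Aquantile normalisation. For a saturated channel the bound is the smallest fold among both arrays under these levels and under the scanner's ratios.

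Genes were named by a rule: those with the 5 smallest p in each direction of the averaged test (used because fewer than 5 passed), the 6 highest and 6 lowest called genes per time point, up to 4 members per gene list with the largest averaged log2 ratio, and a panel of 19 genes of stress response and cardiac function where measured. Of the panel, Gclc, Hspa1b, Hspb1, Myh7 and Col1a1 had no named probe. The tests, the lists and this rule were fixed before the data were examined. Alternatives were normexp and loess in place of the scanner's ratios, centring, other filters on dim probes, another variance model, the deposited series table, other weights and folds, leaving out each array and each time point, and fits on the 6 arrays as separate samples with and without the array letter as a block. The letter gives the dye orientation and not a shared culture. The dye effects of the probes correlated between time points at 0.572 to 0.676 and cancel in a dye-swap mean. Alternatives without saturated probes, and with an estimated correlation and a time left out, were added after the data were seen. In the deposited series table, which holds log10 ratios turned to quercetin over untreated with column medians from -0.00148 to 0.000574, 5 columns equal the scanner ratios of their own array within 1e-05. The column of array A at 12 h equals array A at 24 h instead and was not used.

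The functions were tested on simulated data with spreads drawn from the fitted prior and 100 probes changed by each log2 size. The averaged test on 17903 probes called 82 of 100 probes changed by a log2 of 1 and 95 of 100 changed by 2, with 15 false calls. The slope test called 70 and 96, with 19 false calls. Probes of both sizes were changed in the same run, which eases the adjusted threshold. These shares are therefore not the power of the averaged and slope tests on the real data. The 2-fold rule at 6 h called 33 and 78 and called 69 unchanged probes, more than the 58 probes it called at 6 h in the data. The simulated spread also holds differences between time points, so the 69 do not give the share of false calls among the 58. Figures were drawn with matplotlib 3.10.9.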

Results

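Gene expression was measured in cultured neonatal rat ventricular cells, a primary culture of heart muscle cells, after 6, 12 or 24 h with 30 µM quercetin and set against untreated cells on 6 dye-swapped arrays. Each time point has 2 arrays of the same comparison and counts as 1 replicate, so no difference at a single time point has a replicate check. The SD given with a value at 1 time point is that between the 2 arrays (n = 2, technical). Turned to the same direction, the 2 arrays of a pair correlated across probes at 0.463 at 6 h, 0.213 at 12 h and 0.29 at 24 h, where probes are not independent replicates. The first question of the design is which genes differed between quercetin-treated and untreated cells at each time point.

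At 6 h the highest ratio of a named gene was that of Nqo1, the quinone reductase of the NRF2 antioxidant response, with a log2 ratio of 2.88 ± 0.41. Ednrb, the endothelin receptor type B, was called higher at 2.17 ± 0.05, Osgin1, an oxidative stress-induced growth inhibitor, at 1.98 ± 0.56, and Fosl1, a subunit of the transcription factor AP-1, at 1.69 ± 0.19. The detoxifying enzymes Ptgr1 (1.66 ± 0.09) and Gsta1 (1.66 ± 0.02) were called higher as well. Of the fixed panel, Hmox1, which degrades heme, was called higher at 1.38 ± 0.28, Txnrd1, a thioredoxin reductase, at 1.08 ± 0.14, and Cyp1b1, a classical target of the aryl hydrocarbon receptor, at 1.04 ± 0.20. Bnip3 (1.23 ± 0.03) and the lactate transporter Slc16a3 (1.15 ± 0.06), both of the hypoxia list, were also called. Among lower genes, H1f0, a linker histone, had -1.51 ± 0.09, the steroid dehydrogenase Akr1c14 had -1.50 ± 0.07, and Nppb, which encodes brain natriuretic peptide, had -1.47 ± 0.11, with -1.62 on its other probe. Klf15, a transcription factor of cardiac metabolism, had -1.35 ± 0.18, the growth factor Gdf10 had -1.31 ± 0.02, and Vcam1, an adhesion molecule, had -1.28 ± 0.10. Other called genes, singled out after their values were seen, were Dgkg, Olr1, Gnao1 and Nr4a3 on the higher side and Gja5, Bmp3 and Selenbp1 on the lower. In all, 58 of 19586 probes passed the 2-fold rule, 39 higher and 19 lower, each with the same sign on both arrays. Array A alone gave 72 calls (53 higher, 19 lower) and array B alone gave 75 (36 higher, 39 lower). With a fold of 1.5 the count was 333, and with a fold of 3 it was 11.

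At 12 h the called genes with a symbol were few. Nqo1 (7.97-fold), Gsta1 (log2 ratio 2.49 ± 0.21), Ptgr1 (2.35 ± 0.02) and Osgin1 (2.03 ± 0.03) were called higher. Il1rl1, the receptor of interleukin 33, was called lower at -1.38 ± 0.07, Olr1, a scavenger receptor for oxidised lipoprotein, at -1.37 ± 0.03, and the metallothionein Mt1 at -1.08 ± 0.04. Olr1 had been called higher at 6 h (1.23 ± 0.02) and was the probe called in opposite directions at different times. The rule called 21 of 18395 probes, 12 higher and 9 lower. With array B alone the count was 44, 15 higher and 29 lower. It was 118 at a fold of 1.5 and 8 at a fold of 3.

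At 24 h the same detoxifying enzymes were called higher: Gsta1 at 2.46 ± 0.20, Nqo1 at 2.26 ± 0.20 and Ptgr1 at 1.64 ± 0.10. They were joined by Mgst1, a microsomal glutathione transferase, at 1.57 ± 0.02, whose ratio had been 0.08 ± 0.05 at 6 h and 1.26 ± 0.08 at 12 h, where it was not tested. Mt1 was called lower at -1.76 ± 0.11, Il1rl1 at -1.32 ± 0.07, Nes, the intermediate filament protein nestin, at -1.31, Olr1 at -1.16 ± 0.02, and Hspa5, the main chaperone of the endoplasmic reticulum, at -1.03 ± 0.02. The rule called 29 of 19251 probes, 15 higher and 14 lower. Array B alone gave 54 calls (12 higher, 42 lower) and array A alone gave 51 (35 higher, 16 lower). The count was 201 at a fold of 1.5 and 8 at a fold of 3.

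Across time points, 7 probes were called at all 3 times, and 6 of them were higher each time. These 6 include Nqo1, Gsta1 and Ptgr1 and, named here from their descriptions in the array files after their values were seen, a glutathione S-transferase P subunit (log2 ratios 1.62, 2.32 and 1.33), a glutathione S-transferase Yc2 subunit (1.36, 2.25 and 2.10) and the Smhs1 protein (1.21, 1.64 and 1.44). Glutathione S-transferases are close paralogs, and their probes may share signal, so the family member behind each value is uncertain. Of probes called higher, 9 were shared between 6 and 12 h against 0.024 for independent lists, 7 between 6 and 24 h against 0.03, and 6 between 12 and 24 h against 0.0079. Of probes called lower, 8 were shared between 12 and 24 h against 0.007, and 0 were shared between 6 h and either later time. Part of this excess may come from an untreated RNA that the comparisons share.

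**Figure D1:**
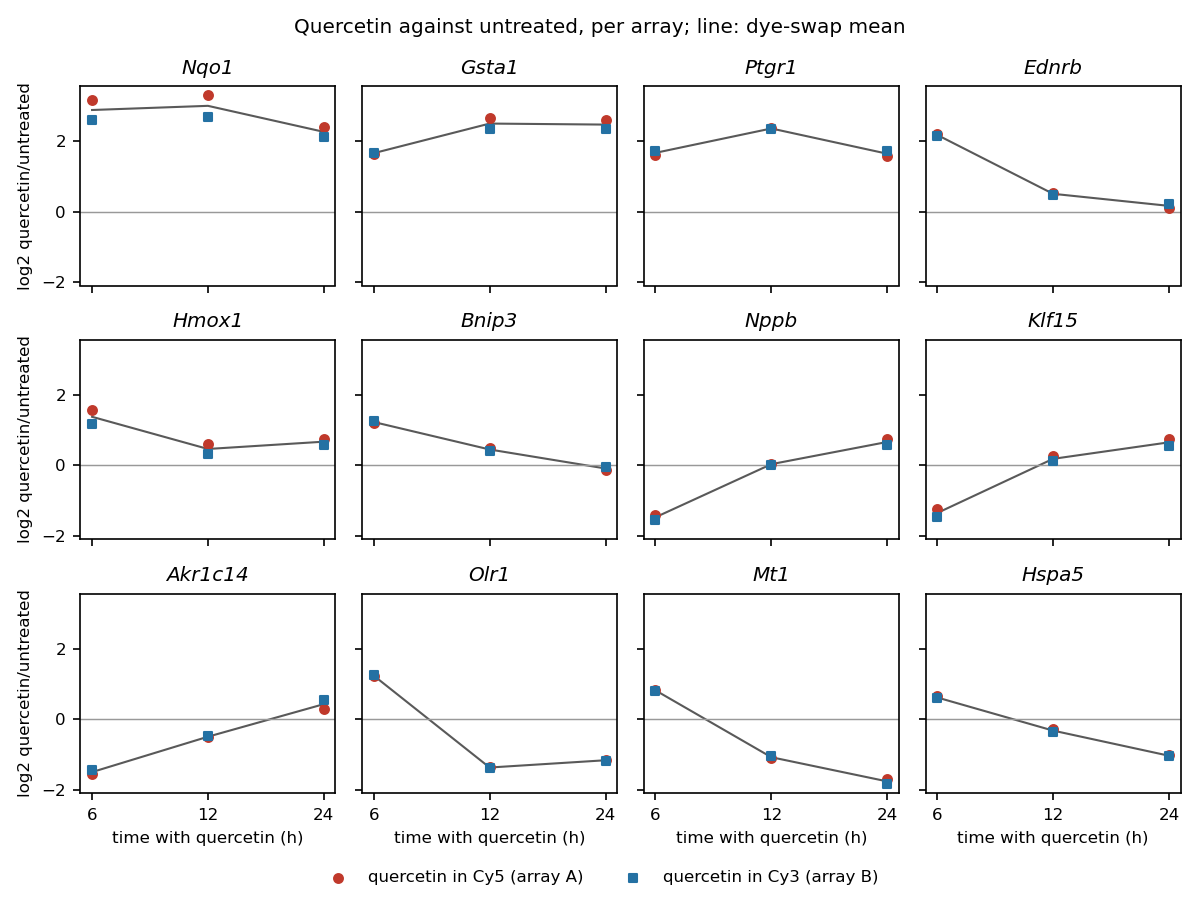
Log2 ratio of quercetin-treated over untreated cells (vertical axis) at 6, 12 and 24 h (horizontal axis) for 12 genes, with circles for the array with quercetin in Cy5, squares for the array with quercetin in Cy3, and a line through the dye-swap means. Nqo1, Gsta1 and Ptgr1 lie above 0 at each time, Nppb goes from -1.47 at 6 h to 0.66 at 24 h, and Mt1 goes from 0.82 to -1.76.

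The next question was which genes differed in the same direction over the 3 times. Nqo1 had the smallest p of the averaged test, with a mean log2 ratio of 2.71 ± 0.16 (SE, n = 3 dye-swap means, positive on 6 of 6 arrays) and an adjusted p of 0.215 in limma. Gsta1 averaged 2.20 ± 0.18, Ptgr1 1.89 ± 0.16, the potassium channel gene Kcnj2 0.97 ± 0.08 and Star, a cholesterol transporter of mitochondria, 1.17 ± 0.11, each positive on 6 of 6 arrays. Kcnj2 at 12 and 24 h and Star at 6 and 24 h had an RNA that was not well above background on 1 array. The SD between the arrays of a pair lay between 0.69 and 1.02 for Kcnj2 and between 0.28 and 0.66 for Star, a spread that the SE of an average, here and below, leaves out. On the lower side the smallest p belonged to Vsnl1, a calcium sensor, at -0.55 ± 0.07, Gckr at -0.50 ± 0.08, the neuropeptide gene Gal at -0.64 ± 0.11, Hipk3 at -0.37 ± 0.07 and Zfp382 at -0.42 ± 0.08. Vsnl1, Gal and Zfp382 were negative on 6 of 6 arrays, while Gckr, with 1 array not well above background at 24 h, was positive on 2 arrays and Hipk3 on 1. No gene passed the threshold, with 0 of 17903 probes called by limma, 1449 at an unadjusted p under 0.05 (825 higher, 624 lower) and 895 expected by chance. The 895 hold for 3 independent means, which a shared untreated RNA would not give. With the sign of 6 h turned, 2016 probes had such a p, so the 1449 are not a count of effects. Without 6 h, 11 probes passed (3 higher, 8 lower), Gsta1 and Il1rl1 among them, and without 24 h or without array A at 12 h 1 probe passed, Nqo1. Fits on the 6 arrays as samples count the 2 technical arrays of a pair as separate replicates. Under them 180 probes passed with the array letter as a block and 100 without it.

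Among the gene lists, the NRF2 targets, genes of antioxidant defence and detoxification, had the highest median of the averages over times, 0.463. All 18 measured members had a positive average, and the list rose relative to the other genes (camera adjusted p = 3.13e-15, adjusted p = 0.908 with an estimated correlation). Against no change, which is what fry tests here and below for members moving in 1 direction, its adjusted p was 0.289. Its median was 0.41 at 6 h, 0.66 at 12 h and 0.32 at 24 h, each at the 100th percentile of random lists. Adjusted over the list alone, 12 members passed, all higher, against 0 over all genes. Beside Nqo1 and Gsta1, the members with the largest averages were Akr7a3, an aflatoxin aldehyde reductase (0.74 ± 0.18), and the ferritin heavy chain Fth1 (0.66 ± 0.12). The ferritin light chain Ftl1 was saturated in the quercetin channel and was at least 1.4-fold higher at 6 h, 1.38-fold at 12 h and 1.44-fold at 24 h. Gclm, a subunit of the enzyme that makes glutathione, averaged 0.16 ± 0.08, and Gsta2 averaged 0.29 ± 0.15. By the 2-fold rule, among the members tested at each time, 5 of 22 were called higher at 6 h, 3 of 19 at 12 h and 3 of 21 at 24 h. Members not tested included Mgst1 (log2 ratio 1.26) and Hmox1 (0.46) at 12 h and Osgin1 (1.31) at 24 h, so the counts are not a time course.

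Genes of glycolysis and the hypoxia response rose as a list relative to the other genes (23 measured, 21 with a positive average, camera adjusted p = 1.41e-06, adjusted p = 0.908 with an estimated correlation). By fry the adjusted p was 0.52. The median was 0.35 at 6 h and 0.34 at 12 h, both at the 100th percentile, and -0.05 at 24 h. Slc16a3 had 1.15, 0.47 and -0.08 at 6, 12 and 24 h, Bnip3 had 1.23, 0.45 and -0.09, and Ero1a, an oxidase of the endoplasmic reticulum, averaged 0.46 ± 0.08. Higd1a averaged 0.33 ± 0.14. Adjusted over the list alone 0 members passed.

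Cholesterol synthesis genes and other SREBP2 targets fell as a list relative to the other genes (19 measured, 19 with a negative average, camera adjusted p = 0.000229, adjusted p = 0.908 with an estimated correlation). By fry the adjusted p was 0.802. The medians were -0.22, 0.04 and -0.32 at 6, 12 and 24 h. Hmgcs1, an early enzyme of the pathway, had -0.42 ± 0.11, -0.13 ± 0.05 and -0.67 ± 0.17, and Fdps, Cyp51 and Sqle averaged -0.34 ± 0.13, -0.33 ± 0.11 and -0.32 ± 0.13. Adjusted over the list alone 0 members passed. Without 24 h the list had an adjusted p of 0.156, with a range of 1.47e-11 to 0.908 over the alternatives.

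Fibroblast and matrix genes fell as a list relative to the other genes (16 measured, 14 with a negative average, camera adjusted p = 0.0409, adjusted p = 0.908 with an estimated correlation). By fry its adjusted p was 0.52, and 4 of the 16, Bgn, Col1a2, Fn1 and Vim, were saturated in both channels. Osteopontin, Spp1, averaged -0.35 ± 0.06, was negative on 6 of 6 arrays and was the 1 member that passed when adjusted over the list alone. Timp3, Fbn1 and Igfbp3 averaged -0.33 ± 0.17, -0.27 ± 0.08 and 0.27 ± 0.16. Smooth muscle and pericyte markers fell as a list relative to the other genes too (8 measured, 7 with a negative average, camera adjusted p = 0.0456, adjusted p = 0.908 with an estimated correlation). By fry its adjusted p was 0.52, with Mcam at -0.41 ± 0.15, Cspg4 at -0.18 ± 0.14, Rgs5 at -0.17 ± 0.20 and Actg2 at -0.16 ± 0.10. Mcam was negative on 6 of 6 arrays and Cspg4 on 4, while Rgs5 and Actg2 were positive on 3. The 2 arrays of Actg2 had opposite signs at each time. The call of the smooth muscle list was lost without 6 h (camera adjusted p = 0.129), without 12 h (0.179) and without 24 h (0.0566). That of the fibroblast list was lost without 12 h (0.343) and without 24 h (0.0719). Over the alternatives the adjusted p ranged from 0.0121 to 0.908 for the smooth muscle list and from 0.00873 to 0.908 for the fibroblast list.

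The remaining 21 tested lists did not pass, with camera adjusted p from 0.13 to 0.927. Cardiomyocyte contractile and calcium genes had medians of -0.10, -0.03 and 0.09 at 6, 12 and 24 h, and 1 member, Kcnj2, passed when adjusted over the list alone. Myh6, the alpha myosin heavy chain, had -0.44 ± 0.01, -0.15 ± 0.03 and 0.10 ± 0.01, Casq2 averaged -0.33 ± 0.14, and the troponin gene Tnnt2 averaged 0.02 ± 0.11. Of the hypertrophy and fetal list (averaged median -0.13), Edn1 averaged -0.30 ± 0.20, Ankrd1 -0.14 ± 0.19 and Nppa -0.13 ± 0.07, while Ccn2 was saturated in the untreated channel and at least 1.23-fold lower at 6 h. At 6, 12 and 24 h Edn1 had -0.84, -0.26 and 0.20, and Ankrd1 had -0.70, 0.13 and 0.15. The median of this list was -0.176, -0.0236 and 0.00787, at percentiles 2.155, 30.07 and 51.35. Markers of other cell types had averaged medians of -0.02 (endothelial), 0.04 (macrophage and leukocyte) and 0.00 (Schwann and neuronal). Nefl of the last list was not well above background with quercetin at 24 h and was at least 1.53-fold lower there. Sox10 averaged 0.52 ± 0.07, with an SD between the arrays of a pair of 0.185 to 0.529. The blood and epicardial lists had 4 and 3 measured genes and were not tested, with Aldh1a2 of the latter at -0.59 ± 0.16.

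Proliferation genes had medians of -0.44, 0.32 and -0.21 at 6, 12 and 24 h over 7 genes, among them Top2a (-0.51, 0.19 and -0.71) and Cdk1 (-0.53, 0.46 and -0.21), and the list passed without 12 h (adjusted p = 3.52e-05, adjusted p = 0.882 with an estimated correlation). NF-kB and inflammatory genes had medians of 0.04, -0.24 and -0.03, and without 6 h the list passed (adjusted p = 0.0022, adjusted p = 0.835 with an estimated correlation), with Ccl20 averaging -0.51 ± 0.20, Il1b -0.34 ± 0.10 and Ccl2 -0.33 ± 0.18. Antioxidant enzymes outside the NRF2 list had medians of -0.07, 0.20 and 0.17, passed without 6 h (adjusted p = 0.041, adjusted p = 0.835 with an estimated correlation) and had 2 members that passed when adjusted over the list alone, catalase (Cat, 0.60 ± 0.10) and Sod3 (0.40 ± 0.08), while Sod2 averaged 0.06 ± 0.08. The p53 targets had medians of 0.03, 0.18 and 0.28 and passed without 6 h (adjusted p = 0.0471, adjusted p = 0.835 with an estimated correlation), with Bax at 0.33 ± 0.08 and Plk2 at -0.36 ± 0.11. Immediate early genes had medians of 0.09, -0.15 and 0.08 and passed without 12 h (adjusted p = 0.0165, adjusted p = 0.882 with an estimated correlation). Metal-responsive genes had medians of 0.44, which was above that of the NRF2 targets at 6 h, -0.11 and 0.09, and 2 members of the list, Fth1 and Ftl1, passed when adjusted over the list alone. Of the aryl hydrocarbon receptor targets, whose averaged median was -0.01, Cyp1b1 passed when adjusted over the list alone (0.69 ± 0.13) and Cyp1a1 averaged 0.02 ± 0.08. Heat shock genes had medians of 0.15, -0.03 and -0.11, with Hspa1a at 0.48 ± 0.03 at 6 h and -0.42 ± 0.10 at 24 h. Over their alternatives the adjusted p of the lists that passed without a time point had a lowest value at that setting and a highest value between 0.908 (p53 targets) and 0.993 (immediate early genes). The unfolded protein response list had -0.10, -0.21 and 0.08, with Calr at 0.17, -0.68 and -0.85.

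The other lists had averaged medians of 0.03 for fatty acid oxidation, 0.04 for oxidative phosphorylation, 0.04 for the ubiquitin-proteasome system, 0.03 for apoptosis genes, 0.02 for interferon response genes, 0.00 for adrenergic, PI3K and MAPK signalling genes and -0.04 for cytosolic ribosomal proteins. Of the 31 ribosomal protein genes, 17 were saturated in both channels, and the median without them was 0.01. Median and mean of the averages had opposite signs in 7 lists. The test followed the median for heat shock genes (median 0.0047, mean -0.0104), cardiomyocyte genes (-0.0398 and 0.0104) and endothelial markers (-0.0181 and 0.00404), and the mean for aryl hydrocarbon receptor targets (-0.00929 and 0.0268), metal-responsive genes (-0.15 and 0.0156) and immediate early genes (-0.00423 and 0.0111). The untested epicardial list had a median of 0.0614 and a mean of -0.13. The Schwann and neuronal list had 2 members and the epicardial list 1 that passed when adjusted over the list alone.

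**Figure D2:**
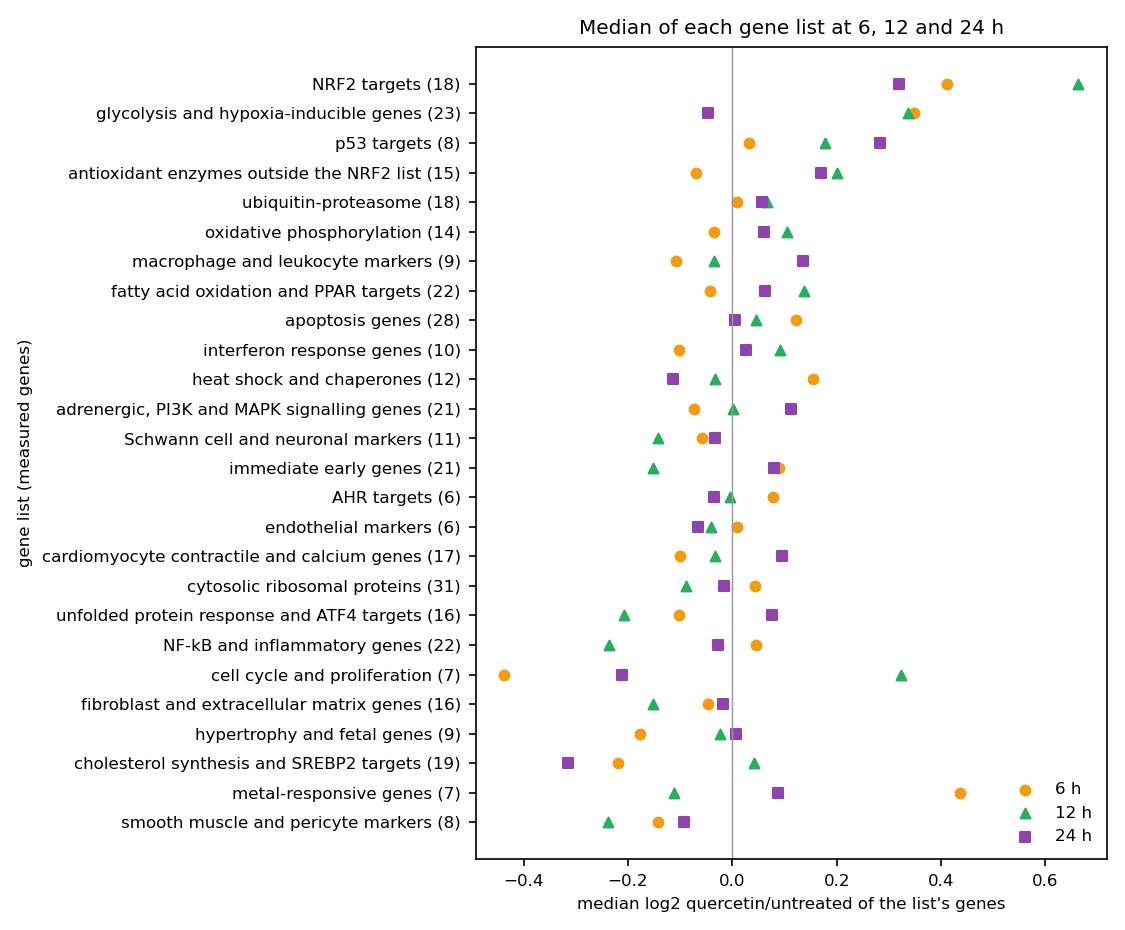
Median log2 ratio of quercetin-treated over untreated cells (horizontal axis) for each tested gene list (vertical axis, with the number of measured genes) at 6 h (circles), 12 h (triangles) and 24 h (squares). The NRF2 targets have medians of 0.41, 0.66 and 0.32, and the proliferation genes lie at -0.44, 0.32 and -0.21.

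The time course asks whether effects grew or shrank. Akr1c14 (-1.50, -0.50 and 0.43 at 6, 12 and 24 h), Nes (0.57, -0.48 and -1.31) and Hspa5 (0.61, -0.32 and -1.03) were among the genes that shared the smallest adjusted p of the slope on log2 time, 0.0994 in limma. Nppb had a slope of 1.07 per doubling of time (adjusted p = 0.113) and Mt1 one of -1.29 (adjusted p = 0.113). No slope passed the threshold, with 0 of 17903 probes called, 2269 at an unadjusted p under 0.05 and 895 expected by chance. With probes well above background in both channels of all 6 arrays, 72 slopes passed (30 higher, 42 lower). With the 6 arrays as samples, which counts each pair as 2 replicates, 1271 passed with the array letter as a block and 521 without it.

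The levels in each channel showed in which RNA such ratios moved. Between 6 and 24 h, 176 of 17903 probes differed by 2-fold or more in the quercetin channel and 0 in the untreated channel. For Mt1 the quercetin channel covered a log2 range of 2.57 over the 3 times and the untreated channel 0.06. The mean square between times was 4.83 times the residual in the quercetin channel and 1.45 times in the untreated channel.

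**Figure D3:**
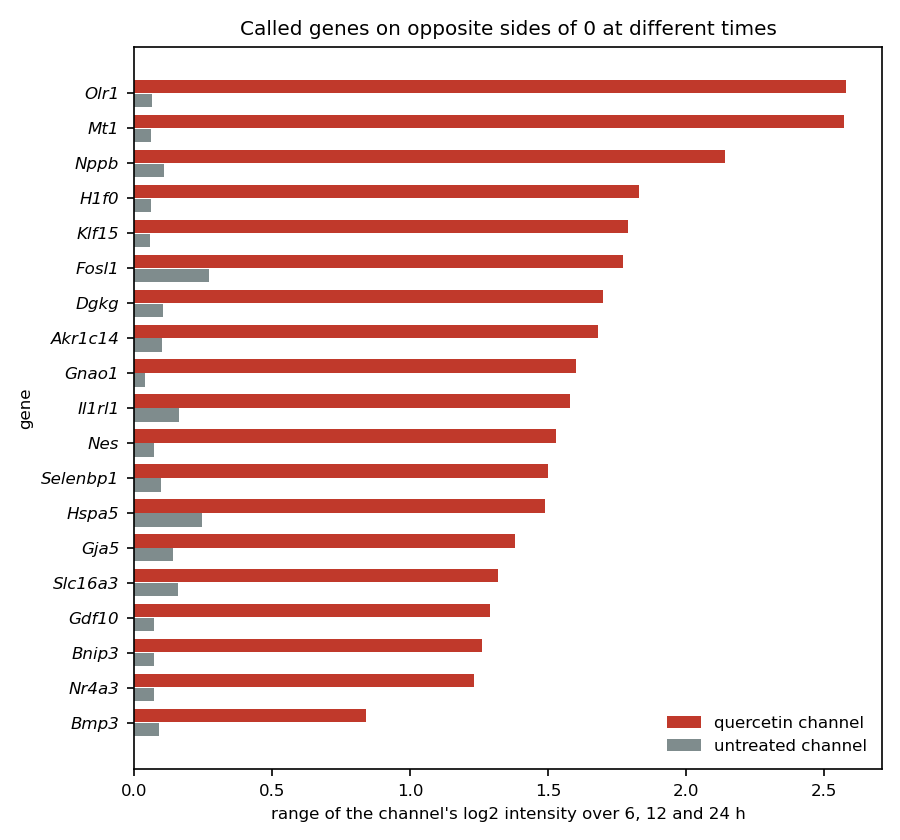
Range of the log2 intensity over 6, 12 and 24 h (horizontal axis) in the quercetin channel and in the untreated channel (paired bars) for 19 called genes tested at all 3 times (vertical axis) with both arrays of 1 time above 0 and both arrays of another below 0. The quercetin channel covered 0.842 to 2.58 and the untreated channel 0.0406 to 0.271.

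Across 17903 probes the dye-swap means of 12 and 24 h correlated at a Pearson r of 0.426 (Spearman 0.4), those of 6 and 12 h at 0.0791 (0.0188) and those of 6 and 24 h at -0.0994 (-0.109). Probes are not independent replicates. A simulation of unchanged RNAs against 1 shared untreated RNA gave r of 0.407 to 0.417. The covariance was 0.0201 for 12 and 24 h against 0.0221 simulated, 0.00442 for 6 and 12 h against 0.0215, and -0.00533 for 6 and 24 h against 0.0217. Between arrays of opposite dye orientation the r of 12 and 24 h was 0.053 and 0.00961.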

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

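The tests of the untreated level, of time in culture and of the slope in these genes were chosen after their values had been seen. For 19 genes with a symbol that the 2-fold rule called at a time point and that were tested at all 3 times, both arrays of 1 time lay above 0 and both arrays of another lay below 0. This difference between times was not tested beyond the slope, which none of the 19 passed in the main setting. The condition uses the sign alone, and only 1 probe, that of Olr1, was called in opposite directions. For some of the 19 the other side lay near 0, as at 24 h for Bnip3 (-0.0876), Slc16a3 (-0.0829) and Bmp3 (0.0809). Such values are a return towards 0 rather than a reversal. With probes well above background in both channels of all 6 arrays, 72 slopes passed over all probes. The distance between the highest and the lowest dye-swap mean, on the log2 scale, was 2.91 for Dgkg, 2.6 for Olr1, 2.58 for Mt1, 2.13 for Nppb, 2.0 for Klf15, 1.98 for Gdf10, 1.92 for Akr1c14, 1.89 for Nes, 1.82 for H1f0 and 1.78 for Fosl1. It was 1.77 for Il1rl1, 1.7 for Gnao1, 1.65 for Hspa5, 1.61 for Gja5, 1.55 for Selenbp1, 1.49 for Nr4a3, 1.32 for Bnip3, 1.23 for Slc16a3 and 1.16 for Bmp3. These are the scanner's ratios. On the normalised channel levels used for the untreated share, Dgkg covered 1.6 and Gdf10 1.31, below the 2.55 of Olr1. Dgkg, Olr1, Mt1, Nes, Il1rl1, Gnao1, Hspa5, Nr4a3, Bnip3 and Slc16a3 had means above 0 at 6 h and below 0 at 24 h. Nppb, Klf15, Gdf10, Akr1c14, H1f0, Gja5, Selenbp1 and Bmp3 had the opposite order, and Fosl1 was 1.69 at 6 h, -0.09 at 12 h and 0.06 at 24 h.

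A drifting untreated level is argued against as the source of these turns, since the range of the untreated channel was at most 0.271 in any of the 19 genes and its share of the ratio's range had a median of 0.0592. A pair of readings of the movement in the quercetin channel stays open. The treated cells may have moved with time in culture, with feeding or with harvest, apart from quercetin. The untreated channels hardly differed between time points, as 1 shared untreated RNA would give. Their mean square between times was 1.45 times the residual, against 4.83 in the quercetin channels. The labels do not say whether the untreated RNA was shared. If it was, this reading cannot be told apart from quercetin. If each time had untreated cells of its own, their flat level would argue against time in culture. A response to quercetin that fades or turns with time is the other reading. The smallest adjusted p of the slope in limma among the 19 genes was 0.0994 in the main setting. It cannot decide, since time in culture would give a slope too and the genes were picked for their turn.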

How the results depend on the processing

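The alternatives without saturated probes and with an estimated correlation and a time left out were chosen after the data had been seen. The averaged test called 0 probes under normexp and loess, centring, both filters on dim probes, the trended robust variance and error weights. It called 1 with the series table, where 12 h came from array B alone, as did the scanner's ratios without array A at 12 h. It called 180 with the replicate block and 100 with the 6 arrays unblocked, both counting each pair as 2 replicates. With an array or a time left out it called 0 to 11. The slope gave 72 with the strict filter, 1271 with the block and 521 unblocked, and 0 under every other setting. The 2-fold counts of 58, 21 and 29 became 39, 14 and 20 with normexp and loess under another rule (2-fold mean, 1.5-fold on each array, no p), 43, 15 and 25 with the rule on each array, 333, 118 and 201 at a fold of 1.5 and 11, 8 and 8 at a fold of 3, and with 1 array alone 72 to 75, 18 to 44 and 51 to 54. The cause was not tested, except that a lower fold admits more probes and a single array keeps its dye effect. The gene lists past the threshold were 5, but 0 with an estimated correlation and 0 by fry in 1 direction. They were 2 to 7 with a time left out and 0 with both an estimated correlation and a time left out. They were 5 under the block and without saturated probes. Fry for members changed in either direction gave an adjusted p of 0.0484 for the NRF2 targets. It gave 0.0448 for each of the cardiomyocyte, endothelial, Schwann and neuronal, and metal-responsive lists, none of which passed camera.

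The correlation of 6 with 12 h was -0.036 with normexp and loess, 0.12 unfiltered, 0.0498 strictly filtered, 0.223 and 0.255 on arrays A and B alone, and -0.164 and -0.106 between opposite orientations. That of 6 with 24 h was -0.215, -0.041, -0.143, 0.121, 0.159, -0.306 and -0.25 in the same order. That of 12 with 24 h was 0.462 with normexp and loess, 0.366 unfiltered, 0.483 and 0.519 on arrays A and B alone, and 0.053 and 0.0096 between opposite orientations, where a shared dye effect enters with opposite sign by construction.

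Among named genes and lists no called direction reversed. Over the alternatives, 467 values of named genes at a time point moved by no more than the SD of the 2 arrays and 30 by more. Of the averaged values of named genes 2242 kept sign and side of the threshold, 32 passed it and 59 not past it took the other sign. For lists these counts were 264, 5 and 38, and 31 list results lost the threshold. Signal over background limits the dimmest genes, such as Nefl at 24 h.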

Other observations

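Some called probes without a symbol were singled out from their file descriptions after their values were seen. A probe for the heme oxygenase gene had log2 ratios of 1.88, 0.63 and 0.77 at 6, 12 and 24 h, beside 1.38, 0.46 and 0.67 for Hmox1. Both tenascin probes, of a matrix glycoprotein, went from 0.33 and 0.15 at 6 h to -1.01 and -1.22 at 12 h and -1.52 and -1.23 at 24 h. A probe for metallothionein 1 and 2 had 0.91, -1.37 and -1.88, next to 0.82, -1.08 and -1.76 for Mt1. A probe similar to annexin A8 had 0.04, -1.46 and -1.59.

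The tests without glutathione S-transferases, of the covariances, of the dye effect and of the turned probe counts were chosen after the values had been seen. The rise of the NRF2 list relative to the other genes is not carried by the transferases that share sequence: without Gsta1, Gsta2, Gstm1 and Gstm5 the 14 other members gave a camera p of 6.4e-15, with 14 of 14 above 0. Nor is it carried by a few strong members, since without Nqo1, Gsta1, Akr7a3 and Fth1 the remaining 14 gave a camera p of 1.2e-10 and a median of 0.349. With an estimated correlation the unadjusted camera p values were 0.0705 and 0.0673, against 0.0621 for the whole list, so the rise holds only under the preset correlation. What raised the list was not tested.

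Noise of a shared untreated RNA adds the same covariance to each pair of times, so on its own it is argued against for the distance of 6 h from the others: the covariance of 12 with 24 h exceeded that of 6 with 24 h by 0.0254. For the likeness of 12 and 24 h it stays open. Their covariance differed by -0.002 from the value simulated for unchanged RNAs with a shared untreated RNA, and a like response at both times cannot be told apart from it. A dye effect left in the means is argued against as the source of this likeness. The dye effect measured on the 6 h arrays correlated with the 12 and 24 h means at -0.05 and -0.0585, which gives 0.00474 of their r of 0.426.

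With the sign of 1 time point turned, 4 splits of the 3 means exist, too few for a share under 0.05. The real split gave 1449 probes at an unadjusted p under 0.05 and the highest other 2016, with 6 h turned, so that 2 of the 4 gave as many. The gene lists past the threshold were 5 in the real split and 5 in the highest other, 2 of the 4.

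Dbp, a clock-controlled transcription factor, had -0.78 ± 0.12, -0.06 ± 0.25 and 0.83 ± 0.14 at 6, 12 and 24 h, and Per2 had -0.04 ± 0.02, -0.50 ± 0.03 and 0.54 ± 0.04. A hypothesis was that the clock phase of the treated cultures differed between harvests. Of 5 clock genes measured besides Dbp, with Per2 among them, 4 had the sign of the difference between 24 and 6 h that this needs. Clock, counted among these 4, differed by only -0.0121. The median signed difference of the 5 was 0.169, at percentile 89.44 of random matched lists, which leaves the hypothesis undecided.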
